A study of Arabidopsis thaliana with 12 samples.

How the data were processed

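Transcript levels were measured on Affymetrix ATH1 arrays in complete Arabidopsis thaliana rosettes of wild-type Col-0 and of the ataf1-1 mutant in the same ecotype, each un-inoculated and 12 h after inoculation with Bgh. Per the labels, plants were at growth stage 3.90, 8 rosettes made 1 sample, and plants had been grown at 20 to 22 °C in 8 h of light at 125 uE per m2 per s and 16 h of dark. Each of the 4 groups held 3 arrays, 12 in all. The labels do not say whether the samples of a group came from separate plantings, so p-values measure only the spread between these samples, which may be technical.

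The deposited values are an intensity per probe set, the linear MAS5 signal the authors computed from biotin-labelled target. The version of MAS5 and its scaling target are not given in the sources used here. All values were above 0, the smallest being 0.077. Each array had been scaled alike, since the mean signal without the lowest and highest 2% of probe sets was 500.3 on every array. The 3 arrays of each group limit the precision of every value.

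Of 22810 probe sets, 64 controls were set aside, and of the remaining 22746 the upper 60% by mean log2 signal over all arrays were tested, a filter blind to group. No detection calls were used, so a group mean under the filter's limit is not shown to be above background. This left 13648 probe sets with a mean signal above 79.4. The log2 signal was used with no further normalization between arrays. Models were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 was loaded) on all 12 arrays with 1 mean per group, followed by empirical Bayes moderation with an intensity trend. There were 8 residual degrees of freedom and a prior of 5.96. In the alternative with the replicate number as a block, that number was added to the model as a fixed effect. The contrasts were the response to Bgh in each genotype, the difference between genotypes in each state, the interaction (the response in ataf1-1 minus that in wild type), and the average effect of Bgh and of genotype. Tests were two-sided. P-values were adjusted by Benjamini-Hochberg over all tested probe sets within a contrast, and a probe set was called at an adjusted p under 0.05. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, which is why the spread was shared between probe sets and groups. Values in the text are log2 changes with their standard error (SE) from this fit, or group means of the signal with the standard deviation (SD) over 3 arrays.

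Probe sets were named from a table that pairs probe sets with genes. It listed 14016 probe sets, 13513 of them with 1 gene and 503 with several, and 8730 were used without a gene name. Symbols came from a gene table of the reference annotation, which held 13436 of the single-gene probe sets and lacked 77. Of the tested probe sets, 7344 named 1 gene, for 7256 genes. ATAF1, AAO3, NCED3, RD29A, PR1, PEN1, PEN2, PEN3, PMR4 and PAD3, which were to be given in every comparison, were not analysed here.

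The following were fixed before the data were examined: the grouping, the filter, the model, the contrasts, the threshold, 28 gene lists, the rule for the genes the text names and the alternative settings. That rule took, per contrast, the 6 largest rises and 6 largest falls among called probe sets that name 1 gene and whose groups did not overlap (not asked of the interaction). It also took up to 3 called members of each list by adjusted p, or at most the 1 member with the smallest p, given as not passing, where none was called. PDF1.2 was given in every contrast. The text describes fewer than the rule takes, and adds probe sets of the average genotype effect, which were chosen after their values were seen. Probe sets without a gene name are described as such.

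Of the 404 members written in the 28 fixed lists 47 had a probe set in the naming table and 38 of these passed the signal filter and were tested, and 4 of these lists had the 3 measured members needed for a test. A further 23 lists were therefore added from gene symbols alone after the naming table was read and before the values of their genes were, and 21 of them had 3 measured members. Members overlap between fixed and added lists of the same theme. Lists of different themes can share members too, as pattern-triggered immunity and calmodulin-like genes share CML37. Such lists are not independent of each other. After the results were seen, the endoplasmic reticulum folding list was also tested without ATCRT1 and the cell division list without FTSZ2-1 and FTSZ2-2, and the nuclear photosynthesis list without GAPC2, which only their symbols had placed there. The list of tricarboxylic acid cycle and citrate genes was likewise tested without 10 genes of ATP citrate lyase, leucine breakdown and electron transfer. In these tests the 4 shorter lists replaced the full ones among the 125. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with 1 probe set per gene, and p-values were adjusted over 125 tests (25 lists in 5 contrasts). Of these, 45 passed. None of the 45 passed with a correlation estimated for each list, where the smallest adjusted p was 0.176. This held also for lists whose estimated correlation was under the preset 0.01. Calmodulin-like genes in wild type (-0.0509) went from an adjusted p of 0.0144 to 0.212, and UDP-glucosyltransferases after Bgh (-0.00787) from 0.00338 to 0.176. Such a failure can thus not be read as the effect of correlation between genes alone. With fry 61 tests passed, and fry asks whether a list's genes move in 1 direction and not whether they do so more than other genes. Camera compares a list with all other tested genes, and the counts of members that rose or fell come from the fit over all probe sets. For lists fixed in advance a count adjusted over the list alone is given as well.

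The method was tested on simulated data in which all 13648 probe sets were drawn with their own mean and spread and no group difference, and a few were then shifted. A shift of 1 on the log2 scale was found for 77.8% of probe sets in a response to Bgh and for 48.7% in the interaction, and a shift of 0.5 for 30% and 4.35%. No called shift had the wrong sign, and between 1.73% and 8.28% of the calls in a contrast were false. Errors were drawn independently, and far fewer probe sets were shifted than passed after Bgh in the real data. These shares therefore need not hold for the real data.

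Alternatives tried were no filter, a filter at the upper 40%, a pseudocount of 4.55 (the 10th percentile), quantile normalization, median centring, no intensity trend, array weights, the replicate number as a block, a 2-fold threshold, only the 2 groups compared, each array left out in turn, and for the lists an estimated correlation and fry. Microarray probes may also read related transcripts, which was not examined. No genome coordinates were used. The labels number the replicates of each group 1 to 3 without saying what a number marks. Arrays with the same number deviated together, with every correlation of residuals over 0.1, between the inoculated genotypes (0.446, 0.132 and 0.258) and between the states of ataf1-1 (0.266, 0.107 and 0.111), and not in the other comparisons.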

Results

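Transcript levels were compared in rosettes of Arabidopsis wild type (Col-0) and of the ataf1-1 mutant, named for ATAF1, a transcription factor of the NAC family. Rosettes were un-inoculated or had been inoculated 12 h earlier with Bgh, in studies of penetration resistance the usual abbreviation of Blumeria graminis f. sp. hordei, a powdery mildew fungus of barley. The series, titled for penetration resistance, asks with a 2 by 2 design how the mutant differs from wild type in its response to the fungus. Each of the 4 groups held 3 arrays, each from 8 rosettes, and 13648 probe sets were tested. The level of ATAF1 itself was not analysed here, so the genotype of each array rests on its label.

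The inoculated arrays were clearly apart from the un-inoculated ones, and the genotypes were much closer to each other. The first principal component carried 80.5% of the variance and put every un-inoculated array on 1 side and every inoculated array on the other. Correlations of log2 signal were 0.828 to 0.864 between un-inoculated and inoculated wild-type arrays, and the mean correlation of an array with the others of its group was 0.968 to 0.982. The median signal was lower after Bgh, at 151 ± 2.58 against 170.3 to 170.6 in wild type and at 153 ± 9.07 against 167 ± 1.1 in ataf1-1 (SD, n = 3). Replicate 1 of inoculated ataf1-1 stood apart from its group, at 41.5 on the first component against 68.2 and 68.4, with a median signal of 163.2 against 146.2 and 149.2. Replicate 1 of inoculated wild type also lay apart, at 45.3 on that component against 58.9 and 59.6. So did replicate 1 of un-inoculated ataf1-1, at -73.05 against -59.4 and -60.8. The actin 3′ to 5′ signal ratio, a sign of RNA quality, was 2.35 ± 0.0874 and 2.3 ± 0.172 in wild type before and after Bgh, and 2.47 ± 0.106 and 2.14 ± 0.191 in ataf1-1. That of GAPDH was higher after Bgh, at 0.919 ± 0.0511 against 0.797 ± 0.0362 in wild type, without overlap of the arrays, and at 0.981 ± 0.126 against 0.783 ± 0.049 in ataf1-1. The 25S rRNA probe set read 859.2 on replicate 1 of un-inoculated ataf1-1 and 476.7 and 469.2 on the other replicates of that group.

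**Figure D1:**
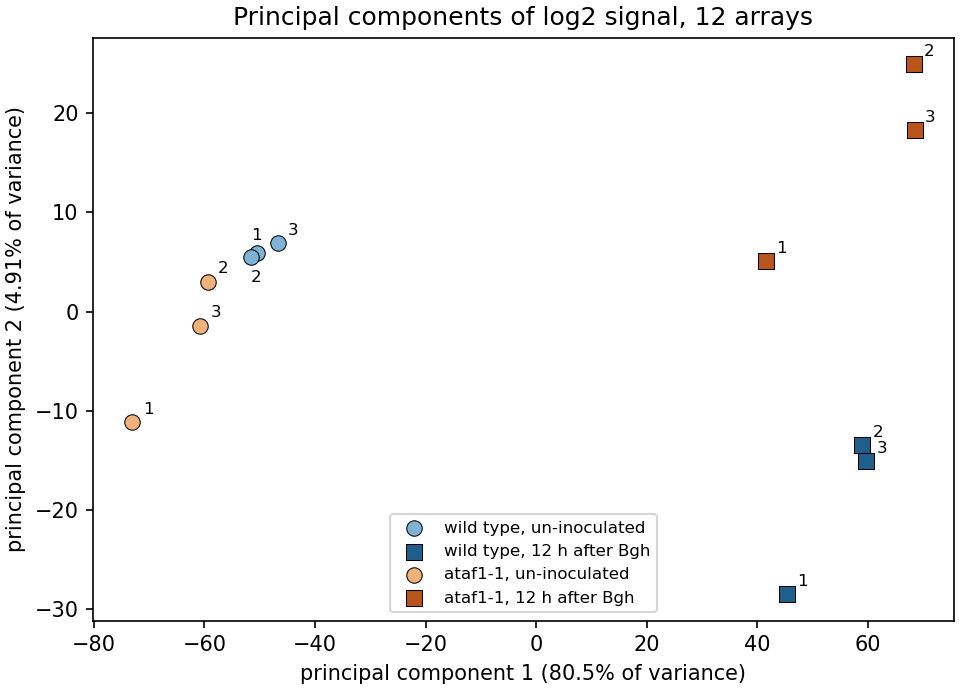
The first 2 principal components of log2 signal over 13648 probe sets, with 1 point per array and colours for the 4 groups. The first component (80.5% of the variance) parted inoculated from un-inoculated arrays, and inoculated ataf1-1 replicate 1 lay at 41.5 while its other replicates lay at 68.2 and 68.4.

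The response of wild type to Bgh was measured as inoculated minus un-inoculated rosettes. The labels name no mock inoculation and give no harvest time for un-inoculated rosettes. Handling and time of day can thus not be told apart from Bgh, in either genotype. Within 12 h 6 of 8 tested genes of pattern-triggered immunity rose and 21 of 23 nuclear photosynthesis genes fell. As lists both passed at the preset correlation between genes, and neither did with an estimated correlation (adjusted p = 0.264 and 0.253). Over all 13648 tested probe sets 3218 rose and 4814 fell. The fixed lists were tested in part only, with 8 of 33 genes written for pattern-triggered immunity and 8 of 33 for photosynthesis. For abscisic acid and dehydration response 4 of 28 were tested, and for endoplasmic reticulum chaperones and secretion 3 of 13. The others had no probe set in the naming table, so they were not analysed and may lie among the probe sets without a gene name. Among the largest named rises were those of UGT71C3 (AT1G07260), a UDP-glucosyltransferase, at 5.55 on the log2 scale (SE 0.57, adjusted p = 1.85e-06), from a signal of 31.4 ± 23.2 to 1049 ± 259 (SD, n = 3), and of AT5G12930, also at 5.55 (SE 0.60). CCR2 (AT1G80820), a cinnamoyl-CoA reductase of lignin synthesis, rose by 5.07 (SE 0.64). The un-inoculated signals of these 3 genes lay under 79.4, the mean asked of a tested probe set, and were not shown to be above background, so the sizes are uncertain (4.55 to 6.15 for UGT71C3 without 1 array). AT1G26380, an oxidase of the berberine bridge enzyme family, rose by 4.89 (SE 0.21), from 193.7 ± 50.9 to 5640 ± 604. UGT76B1 (AT3G11340), which glucosylates salicylic acid, rose by 4.78 (SE 0.52). EXPA8 (AT2G40610), an expansin that loosens cell walls, fell by 3.71 on the log2 scale (SE 0.29, adjusted p = 1.46e-07), from 1353 ± 195 to 109.4 ± 47.9. ATSPS4F (AT4G10120), a sucrose phosphate synthase, fell by 2.88 on the log2 scale (SE 0.16), and AT1G12010, an ACC oxidase of ethylene synthesis, from 200.2 ± 10.2 to 21.9 ± 4.0, also under 79.4. The nitrate transporter gene AT3G21670 changed by -3.02 (SE 0.36), AT1G60590 by -3.32 (SE 0.67) and the bHLH factor gene AT4G01460 by -3.02 (SE 0.88). The call of AT4G01460 ended without inoculated wild-type replicate 3, at an adjusted p of 0.0501.

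Of 8 tested genes of pattern-triggered immunity in wild type, 6 rose and none fell, over all genes and adjusted over the list alone, with a median change of 1.34. The list passed (adjusted p = 0.00175), and had an adjusted p = 0.264 with an estimated correlation. Its members included PUB23 (AT2G35930; 2.84, SE 0.31) and PUB24 (AT3G11840; 1.86, SE 0.11), ubiquitin ligases that dampen immune signalling, and BIK1 (AT2G39660; 1.19, SE 0.12), a kinase acting next to immune receptors. In the wider immunity and defence list 13 of 22 genes rose and 2 fell (median 1.17, adjusted p = 0.00021). Its adjusted p was 0.176 with an estimated correlation. WRKY6 (AT1G62300), a factor of senescence and defence, rose by 2.84 (SE 0.17). GRX480 (AT1G28480), a glutaredoxin induced by salicylic acid, rose by 2.75 (SE 0.44). PDF1.2 (AT5G44420) and PDF1.2b (AT2G26020), defensins of jasmonate and ethylene defence, rose by 3.01 (SE 0.61) and 3.08 (SE 0.62), PDF1.2 from 1395 ± 643 to 10940 ± 4050. JMT (AT1G19640), the jasmonate methyltransferase, rose by 1.59 (SE 0.24), and the zinc finger gene STZ (AT1G27730) by 2.08 (SE 0.19). Of 5 calmodulin-like genes 4 rose, among them CML37 (AT5G42380; 2.21, SE 0.41) and CML42 (AT4G20780; 1.76, SE 0.12), with a median of 1.76 and an adjusted p of 0.0144 (adjusted p = 0.212 with an estimated correlation).

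In phenylpropanoid and flavonoid metabolism 6 of 10 genes rose and 3 fell (median 1.18, adjusted p = 0.014), with an adjusted p = 0.228 with an estimated correlation. CCOAMT (AT1G67980), a caffeoyl-CoA methyltransferase, rose by 3.07 (SE 0.20), and HCT (AT5G48930), a hydroxycinnamoyl transferase, by 1.10 (SE 0.12). UDP-glucosyltransferases went both ways, with 12 of 26 up and 8 down (median 0.24, adjusted p = 0.0193; adjusted p = 0.204 with an estimated correlation). UGT73B5 (AT2G15480) and UGT85A2 (AT1G22360) rose by 3.72 (SE 0.21) and 2.49 (SE 0.15). Of 14 exocyst and SNARE genes, which act in vesicle fusion, 9 rose and 2 fell (median 0.61, adjusted p = 0.00641; adjusted p = 0.204 with an estimated correlation). SEC1B (AT4G12120) and ATSLY1 (AT2G17980), of the Sec1 family of fusion regulators, rose by 2.93 (SE 0.23) and 1.01 (SE 0.13). All 3 tested genes of the endoplasmic reticulum chaperone and secretion list rose, also adjusted over the list alone (median 1.02, adjusted p = 0.0282, or 0.278 with an estimated correlation). These were BZIP60 (AT1G42990; 1.38, SE 0.15), a factor of the unfolded protein response, the co-chaperone ATERDJ3B (AT3G62600; 1.02, SE 0.18) and the calreticulin CRT1b (AT1G09210; 0.55, SE 0.14). NDB2 (AT4G05020), an NADH dehydrogenase of mitochondria, rose by 2.63 (SE 0.26).

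In the nuclear photosynthesis list, made from symbols, 22 of 24 genes fell in wild type and none rose (median -0.85, adjusted p = 3.11e-06; adjusted p = 0.264 with an estimated correlation). Without GAPC2, an enzyme of the cytosol and not of photosynthesis, 21 of 23 fell (median -0.86, adjusted p = 3.88e-06; adjusted p = 0.253 with an estimated correlation). The GAPDH 3′ to 5′ ratio rose in the same arrays, from 0.797 ± 0.0362 to 0.919 ± 0.0511, while that of actin was 2.35 ± 0.0874 and 2.3 ± 0.172. In the shorter photosynthesis list fixed in advance 7 of 8 fell, and 8 adjusted over the list alone (median -0.77, adjusted p = 0.00553; adjusted p = 0.268 with an estimated correlation). PRK (AT1G32060), the phosphoribulokinase of carbon fixation, fell by 1.21 on the log2 scale (SE 0.099), from 20160 ± 1060 to 8756 ± 1010. LHCB4.2 (AT3G08940), an antenna protein of photosystem II, fell by 1.12 on the log2 scale (SE 0.10), and NdhN (AT5G58260), of the chloroplast NDH complex, by 1.66 on the log2 scale (SE 0.13; -1.66). Of 13 carboxypeptidase-like genes 12 fell (median -0.90, adjusted p = 0.00317; adjusted p = 0.268 with an estimated correlation), scpl42 (AT5G42240) by -1.63 (SE 0.17) and SCPL34 (AT5G23210) by -1.25 (SE 0.15). STOMAGEN (AT4G12970), a peptide that promotes stomata, changed by -2.48 (SE 0.32) and GSTU18 (AT1G10360), a glutathione transferase, by -1.71 (SE 0.15).

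Abscisic acid and dehydration genes did not move as a group in wild type. Of 4 tested genes in the list fixed in advance 1 fell, COR15B (AT2G42530, -0.61, SE 0.23), and none adjusted over the list alone (adjusted p = 0.801). The call of COR15B ended without un-inoculated replicate 2 or 3 or inoculated replicate 1 or 3 of wild type, with adjusted p up to 0.158. In the added list of 15 such genes 4 rose and 7 fell (adjusted p = 0.962), RD2 (AT2G21620) by 2.13 (SE 0.11) and COR27 (AT5G42900), a cold and clock gene, by -1.78 (SE 0.14). Lists that did not pass in wild type were tau-class glutathione transferases (4 of 4 fell, adjusted p = 0.0592), U-box ligases (4 of 8 rose, 0.0592), ubiquitin proteases and conjugases (8 of 22 rose, 2 fell, 0.0681) and endoplasmic reticulum folding (6 of 14 rose, 2 fell, 0.0702). The tricarboxylic acid cycle and citrate list (8 of 18 rose, 5 fell, adjusted p = 0.155), cell wall expansion (1 of 12 rose, 5 fell, 0.272) and cell division (1 of 13 rose, 5 fell, 0.533) did not pass. Without genes of ATP citrate lyase, leucine breakdown and electron transfer, left out after the results were seen, 6 of 8 genes of the tricarboxylic acid cycle and citrate list rose and 1 fell, and it passed (median 0.75, adjusted p = 0.00403; adjusted p = 0.227 with an estimated correlation). Nor did glucosinolate metabolism (4 of 9 rose, 3 fell, adjusted p = 0.653), the TBL wall acetylation family (4 of 12 rose, 5 fell, 0.716), CYP71B cytochromes (3 of 10 rose, 5 fell, 0.844), SWEET transporters (1 of 5 rose, 2 fell, 0.844) and autophagy (1 of 10 rose, 3 fell, 0.886). Of 66 chloroplast-encoded genes 1 rose and 6 fell (adjusted p = 0.962), with a median of -0.12 and a mean of -0.065 while the test pointed upward against other genes. The median and the mean differed in sign for glucosinolate metabolism (0.11 and -0.058) and the TBL family (0.082 and -0.12). For the CYP71B list the median was -0.36 and the mean -0.027 while the test pointed upward.

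In all, 8032 of 13648 probe sets (58.9%) passed in wild type, 3218 higher and 4814 lower after Bgh, and 2966 of them changed at least 2-fold. The median probe set changed by -0.14, by -0.072 after quantile normalization and by -0.086 after median centring.

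In ataf1-1, too, genes of pattern-triggered immunity rose (8 of 8) and nuclear photosynthesis genes fell (22 of 23), in lists with an adjusted p of 0.228 and 0.227 with an estimated correlation. Single changes were larger than in wild type for some genes and smaller for others, such as RD2 (1.47 against 2.13). AT5G55420 rose by 6.23 (SE 0.71, adjusted p = 3.5e-06), AT4G39670, of the glycolipid transfer protein family, by 6.20 (SE 0.40), AT1G26380 by 6.01 (SE 0.21), from 105.1 ± 31.5 to 6633 ± 962 (SD, n = 3), and UGT76B1 by 5.89 (SE 0.52). AT2G23270 and AT5G12930 rose by 5.86 (SE 0.43) and 5.57 (SE 0.60). AT1G60590 fell by 5.08 on the log2 scale (SE 0.67, adjusted p = 1.37e-05) and ARR15 (AT1G74890), a response regulator of cytokinin signalling, by 3.61 on the log2 scale (SE 0.78; -3.61). AT3G21670, AT5G62140, AT4G17810 and AT5G41900 changed by -3.79 (SE 0.36), -3.49 (SE 0.21), -3.47 (SE 0.55) and -3.30 (SE 0.63). Of the genes named so far in this comparison all but AT4G39670, AT1G26380 and RD2 had a mean signal under 79.4 in 1 state, so the sizes of their changes are uncertain. Of 8 genes of pattern-triggered immunity all 8 rose, also adjusted over the list alone (median 2.09, adjusted p = 0.000137; adjusted p = 0.228 with an estimated correlation). PUB24, BIK1 and CML37 rose by 2.44 (SE 0.11), 1.64 (SE 0.12) and 4.38 (SE 0.41). In the wider immunity list 18 of 22 rose and 1 fell (median 1.77, adjusted p = 7.66e-06; adjusted p = 0.176 with an estimated correlation). SAG101 (AT5G14930), a partner of the immune regulator EDS1, rose by 1.86 (SE 0.22) and GRX480 by 4.11 (SE 0.44). PDF1.2 rose by 1.79 (SE 0.61, adjusted p = 0.0195) and PDF1.2b by 2.53 (SE 0.62). The PDF1.2 call ended without un-inoculated replicate 2 or inoculated replicate 2 or 3 of ataf1-1, with adjusted p up to 0.0638.

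Calmodulin-like genes rose in 4 of 5 cases in ataf1-1 (median 2.04, adjusted p = 0.00673; adjusted p = 0.204 with an estimated correlation), CML42 by 1.98 (SE 0.12). All 3 tested genes of the endoplasmic reticulum chaperone and secretion list rose, also adjusted over the list alone (median 1.61, adjusted p = 0.00869, or 0.264 with an estimated correlation). BZIP60 rose by 2.05 (SE 0.15), ATERDJ3B by 1.61 (SE 0.18) and CRT1b by 1.22 (SE 0.14). In the wider endoplasmic reticulum folding list 9 of 14 rose (median 0.60, adjusted p = 0.00232; adjusted p = 0.264 with an estimated correlation), and 8 of 13 without ATCRT1. Exocyst and SNARE genes rose in 9 of 14 cases and fell in 1 (median 0.49, adjusted p = 0.0122; adjusted p = 0.212 with an estimated correlation), with SEC1B at 3.03 (SE 0.23) and ATSLY1 at 1.10 (SE 0.13). CCR2 rose by 5.09 (SE 0.64), while the phenylpropanoid list as a whole did not pass (6 of 10 rose, 3 fell, adjusted p = 0.0567).

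The genes of the nuclear photosynthesis list fell in 23 of 24 cases in ataf1-1 (median -1.24, adjusted p = 8.24e-07; adjusted p = 0.251 with an estimated correlation), and without GAPC2 in 22 of 23 (median -1.29, adjusted p = 8.24e-07; adjusted p = 0.227 with an estimated correlation). In the list fixed in advance 8 of 8 fell, also adjusted over the list alone (median -1.09, adjusted p = 0.00309; adjusted p = 0.264 with an estimated correlation). SBPASE (AT3G55800), the sedoheptulose bisphosphatase of carbon fixation, fell by 1.38 on the log2 scale (SE 0.087), from 15270 ± 510 to 5872 ± 340, PRK changed by -1.35 (SE 0.099) and NdhN by -2.08 (SE 0.13). Of 66 chloroplast-encoded genes 30 fell and 1 rose (median -0.34, adjusted p = 0.015; adjusted p = 0.586 with an estimated correlation). Among them rbcL, the large subunit of Rubisco, changed by -0.88 (SE 0.14), and the ribosomal protein genes rpl36 and rps15 by -0.63 (SE 0.11) and -0.86 (SE 0.17). Signs of RNA quality moved as well, with the actin 3′ to 5′ ratio at 2.47 ± 0.106 before and 2.14 ± 0.191 after Bgh and that of GAPDH at 0.783 ± 0.049 and 0.981 ± 0.126. In the cell division list 10 of 13 fell (median -0.54, adjusted p = 0.023; adjusted p = 0.355 with an estimated correlation). Those that fell included FTSZ2-1 (AT2G36250; -0.80, SE 0.11) and FTSZ2-2 (AT3G52750; -1.33, SE 0.12), known for division of the chloroplast and not of the cell, and TSO1 (AT3G22780; -1.24, SE 0.15). Without the FTSZ2 genes 8 of 11 fell and the list did not pass (median -0.50, adjusted p = 0.0776). All 4 tau-class glutathione transferases fell (median -1.22, adjusted p = 0.023; adjusted p = 0.228 with an estimated correlation), GSTU18 by -2.12 (SE 0.15) and GSTU20 (AT1G78370) by -1.63 (SE 0.15). Of 13 carboxypeptidase-like genes 11 fell (median -0.95, adjusted p = 0.00309; adjusted p = 0.268 with an estimated correlation), scpl29 (AT4G30810) by -0.86 (SE 0.092).

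In the abscisic acid list fixed in advance 2 of 4 genes fell in ataf1-1, also adjusted over the list alone, COR15A (AT2G42540; -0.91, SE 0.23) and COR15B (-0.81, SE 0.23), and the list did not pass (adjusted p = 0.531). In the added list 4 of 15 rose and 6 fell (adjusted p = 0.987), with a median of -0.37 and a mean of 0.073, and RD2 rose by 1.47 (SE 0.11). U-box ligases (4 of 8 rose, 1 fell, adjusted p = 0.0562), ubiquitin proteases and conjugases (9 of 22 rose, 3 fell, 0.142), cell wall expansion (1 of 12 rose, 8 fell, 0.155), UDP-glucosyltransferases (11 of 26 rose, 10 fell, 0.187) and the tricarboxylic acid cycle and citrate list (7 of 18 rose, 3 fell, 0.195) did not pass. Without the genes named for wild type 5 of 8 rose in the last of these and it passed (median 0.69, adjusted p = 0.0144; adjusted p = 0.253 with an estimated correlation). CYP71B cytochromes (3 of 10 rose, 4 fell, adjusted p = 0.414), autophagy (3 of 10 rose, 2 fell, 0.47), SWEET transporters (1 of 5 rose, 3 fell, 0.531), the TBL family (1 of 12 rose, 5 fell, 0.85) and glucosinolate metabolism (3 of 9 rose, 4 fell, 0.948) did not pass either. The TBL median of 0.024 and mean of -0.36 differed in sign. In ataf1-1, 8352 probe sets passed (61.2%), 3396 higher and 4956 lower after Bgh, and 3613 changed at least 2-fold.

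Across probe sets the responses of the genotypes, which share no array, correlated at Pearson's r = 0.907 and Spearman's rho = 0.883, with an orthogonal slope of 1.19 of ataf1-1 on wild type. Probe sets are not independent replicates, so no p is given. Higher in both were 2645 probe sets, where 800.7 would be shared by independent lists, and lower in both were 3953 against 1748. Only 40 passed in opposite directions. Without the filter on low signal the correlation was 0.61.

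**Figure D2:**
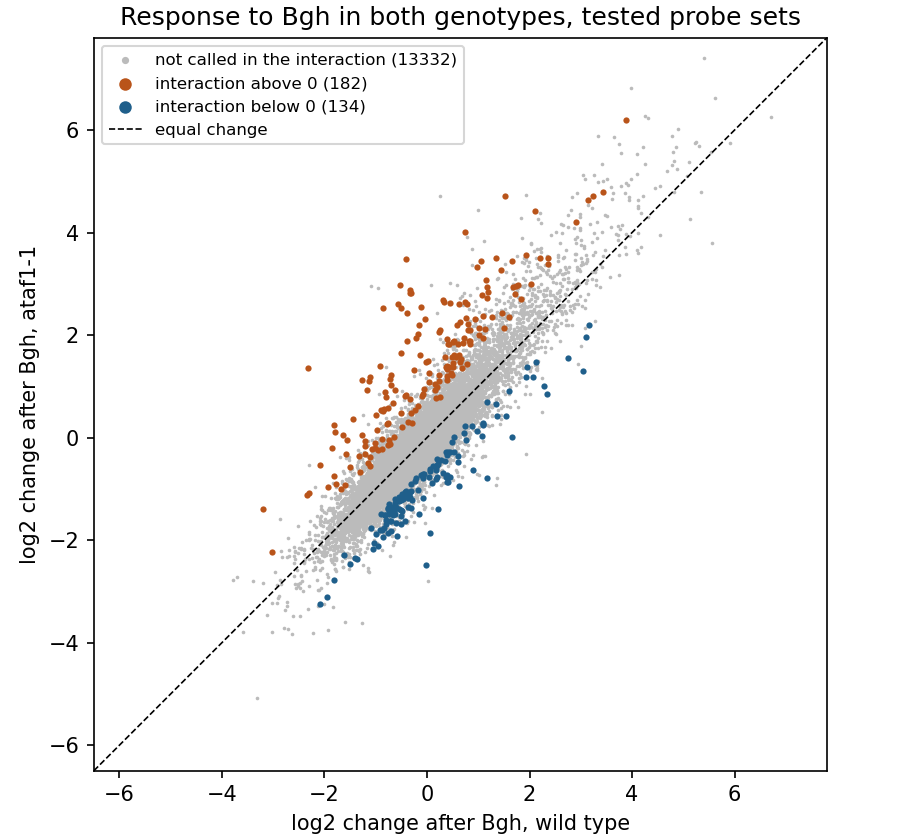
Log2 change after Bgh in ataf1-1 (vertical) against that in wild type (horizontal), 1 point per tested probe set. The orthogonal slope was 1.19 and Pearson's r 0.907.

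Before inoculation the rosettes of the genotypes differed little, and named genes that passed were lower in ataf1-1. AT4G18250, a receptor-like kinase, was lower by -1.37 (SE 0.20, adjusted p = 0.0249), at 43.2 ± 12.5 against 110.6 ± 23.9 in wild type (SD, n = 3). Its signal in ataf1-1 lay under 79.4, so the size of this difference is uncertain. AT1G24140, a matrix metalloproteinase, was lower by -1.28 (SE 0.22, adjusted p = 0.0458), and AT3G23550, a transporter of the MATE family, by -0.75 (SE 0.10, adjusted p = 0.024), at 861.5 ± 133 against 1438 ± 41.2. AT2G15042, AT4G38540 and AT5G64420 were lower by -0.83 (SE 0.14), -0.74 (SE 0.13) and -0.65 (SE 0.11). Immune genes lay slightly lower in ataf1-1 as groups, though no member passed alone, nor adjusted over the list alone where the list was fixed in advance. All 8 genes of pattern-triggered immunity had values below 0 (median -0.29, adjusted p = 0.00784; adjusted p = 0.268 with an estimated correlation). So did 19 of 22 immunity and defence genes (median -0.22, adjusted p = 0.000137; adjusted p = 0.176 with an estimated correlation). Calmodulin-like genes were below 0 in 5 of 5 cases (median -0.28, adjusted p = 0.00689; adjusted p = 0.204 with an estimated correlation), and CYP71B cytochromes in 8 of 10 (median -0.18, adjusted p = 0.0369; adjusted p = 0.228 with an estimated correlation). The members with the smallest p, none of them passing, were SBT3.3 (AT1G32960), a protease of immune priming (-2.71, SE 0.62, adjusted p = 0.119), CML37 (-1.303, SE 0.41, adjusted p = 0.288) and CYP71B23 (AT3G26210; -0.96, SE 0.27, adjusted p = 0.227). PDF1.2 stood at -1.12 (SE 0.61, adjusted p = 0.568). Of 13 cell division genes 11 had values above 0 (median 0.16, adjusted p = 0.00869; adjusted p = 0.31 with an estimated correlation), among them the histone gene HTB4 (AT5G59910; 0.23, SE 0.088, adjusted p = 0.406). Without the FTSZ2 genes the adjusted p of the list was 0.0306 (median 0.16; adjusted p = 0.328 with an estimated correlation). BCAT4 (AT3G19710), of methionine-derived glucosinolate synthesis, stood at 0.55 (SE 0.12, adjusted p = 0.104).

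No other list passed between un-inoculated genotypes, and no member of any list passed alone. Adjusted p was 0.0822 for endoplasmic reticulum chaperones (median -0.23), 0.155 for chloroplast-encoded genes (0.066), 0.181 for autophagy (-0.095), 0.187 for glucosinolate metabolism (0.077), 0.194 for tau-class glutathione transferases (0.049) and 0.259 for UDP-glucosyltransferases (-0.012). It was 0.297 for the photosynthesis list fixed in advance, whose median of -0.080 became 0.026 after quantile normalization, 0.392 for carboxypeptidase-like genes (0.066), 0.47 for the fixed abscisic acid list (0.087) and 0.47 for endoplasmic reticulum folding (-0.077). For the TBL family it was 0.543 (median -0.0065, mean 0.029, median 0.018 after quantile normalization), for phenylpropanoid genes 0.702 (-0.11), for SWEET transporters 0.709 (0.074) and for cell wall expansion 0.716 (0.092, mean -0.023). For nuclear photosynthesis genes it was 0.801 (median 0.024, mean -0.013), for the tricarboxylic acid cycle and citrate list 0.823 (-0.011) and for U-box ligases 0.85 (-0.12). The added abscisic acid list (0.857, median 0.047, mean -0.063), exocyst and SNARE genes (0.962, median 0.0036, below 0 after quantile normalization or median centring) and ubiquitin proteases and conjugases (0.962, median 0.044) had the highest adjusted p.

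Between un-inoculated genotypes 18 probe sets passed, 4 higher and 14 lower in ataf1-1, and 1350 had an unadjusted p under 0.05. Of the 14 lower, 13 rose with Bgh on average over both genotypes and none fell, and of the 4 higher none rose and 2 fell. The count depended on single arrays. It was 1 without wild-type un-inoculated replicate 1 or ataf1-1 un-inoculated replicate 1, 3 without wild-type un-inoculated replicate 2 or 3, and 59 without ataf1-1 un-inoculated replicate 2. It was 8 without any 1 of the inoculated wild-type arrays or inoculated ataf1-1 replicate 2, and 10 without inoculated ataf1-1 replicate 3. None of the 6 named genes passed without each of these arrays, with adjusted p up to 0.179. Array weights gave 69, a fit of these 2 groups alone 1, no intensity trend 1 and no filter 7.

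After Bgh more genes differed between the genotypes. Of 13 endoplasmic reticulum folding genes (without ATCRT1) 3 were higher in ataf1-1 and of 66 chloroplast-encoded genes 5 were lower, in lists with an adjusted p of 0.227 and 0.278 with an estimated correlation. AT1G12010, the ACC oxidase gene, was higher by 1.94 (SE 0.23, adjusted p = 0.000724), AT5G40690 by 1.66 (SE 0.20) and AT5G37540, of the aspartyl protease family, by 1.64 (SE 0.24), sizes that are uncertain because the wild-type signals lay under 79.4 (21.9 ± 4.0 for AT1G12010). CYP71B24 (AT3G26230) was higher by 1.60 (SE 0.21), at 340.5 ± 35.9 against 115.4 ± 34.4 in wild type (SD, n = 3). SAL2 (AT5G64000), a phosphatase of the SAL1 family, was higher by 2.07 (SE 0.45), at 943.2 ± 63.8 against 226.8 ± 39.4, AT1G58420 by 1.77 (SE 0.43) and GLR2.8 (AT2G29110), a glutamate receptor-like channel, by 1.67 (SE 0.44). JAL23 (AT2G39330), a jacalin-like lectin, was lower by -2.23 (SE 0.35, adjusted p = 0.00339), at 112.2 ± 41.7 against 519.5 ± 170. AT1G10585, a bHLH factor, was lower by -1.87 (SE 0.34), AT4G17470 by -1.54 (SE 0.20) and AT1G73600, a phosphoethanolamine methyltransferase of phosphocholine synthesis, by -1.298 (SE 0.12), at 433.9 ± 49.3 against 1065 ± 97.9. SNZ (AT2G39250), a repressor of flowering, was lower by -1.27 (SE 0.26). PDF1.2 was lower by -2.33 (SE 0.61, adjusted p = 0.0426), at 2097 ± 298 against 10940 ± 4050, and PYK10 (AT3G09260), a glucosidase of endoplasmic reticulum bodies and a root marker, by -1.99 (SE 0.47, adjusted p = 0.0279).

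Of 14 genes in the endoplasmic reticulum folding list, which was made from symbols, 4 were higher in ataf1-1 after Bgh and none lower (median 0.39, adjusted p = 0.00021; adjusted p = 0.228 with an estimated correlation). Without ATCRT1 (AT5G56340; 0.93, SE 0.23), a RING finger protein and not a calreticulin, 3 of 13 were higher (median 0.35, adjusted p = 0.00113; adjusted p = 0.227 with an estimated correlation). DER2.1 (AT4G21810), a derlin, was higher by 0.57 (SE 0.12) and OS9 (AT5G35080), a lectin of protein degradation, by 0.59 (SE 0.13). In the chaperone and secretion list fixed in advance none of 3 genes passed over all genes and 3 did adjusted over the list alone (median 0.43, adjusted p = 0.0297, or 0.278 with an estimated correlation). BZIP60 stood at 0.44 (SE 0.15, adjusted p = 0.121, or 0.0416 with the replicate number as a block). Of 8 genes of pattern-triggered immunity 1 was higher, PUB24 (0.47, SE 0.11), and 2 adjusted over the list alone (median 0.28, adjusted p = 0.026; adjusted p = 0.333 with an estimated correlation). Of 66 chloroplast-encoded genes 5 were lower in ataf1-1 and none higher (median -0.24, adjusted p = 8.24e-07; adjusted p = 0.278 with an estimated correlation). In the same arrays the actin 3′ to 5′ ratio was 2.14 ± 0.191 against 2.3 ± 0.172 in wild type and that of GAPDH 0.981 ± 0.126 against 0.919 ± 0.0511. rbcL was lower by -0.62 (SE 0.14), at 1177 ± 188 against 1803 ± 289, rps15 by -0.73 (SE 0.17) and rpl20 by -0.70 (SE 0.14). Of 23 nuclear photosynthesis genes (without GAPC2) 2 were lower (median -0.24, adjusted p = 6.52e-06; adjusted p = 0.253 with an estimated correlation), SBPASE by -0.69 (SE 0.087) and NTRC (AT2G41680), a thioredoxin reductase of the chloroplast, by -0.55 (SE 0.12). In the photosynthesis list fixed in advance 1 of 8 was lower, and 3 adjusted over the list alone (median -0.24, adjusted p = 0.00309; adjusted p = 0.264 with an estimated correlation).

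UDP-glucosyltransferases were lower in 4 of 26 cases (median -0.20, adjusted p = 0.00338; adjusted p = 0.176 with an estimated correlation), UGT84A3 (AT4G15490) by -1.01 (SE 0.18) and UGT78D2 (AT5G17050), which glucosylates flavonoids, by -0.52 (SE 0.14). In the TBL family 3 of 12 were lower (median -0.18, adjusted p = 0.0315; adjusted p = 0.228 with an estimated correlation), TBL26 (AT4G01080) by -1.06 (SE 0.21), TBL38 (AT1G29050) by -0.63 (SE 0.13) and TBL37 (AT2G34070) by -0.39 (SE 0.11). Of 13 cell division genes 2 were lower (median -0.22, adjusted p = 0.0142; adjusted p = 0.333 with an estimated correlation), the histone H2B gene HTB4 by -0.46 (SE 0.088) and FTSZ2-2, of chloroplast division, by -0.49 (SE 0.12). Without the FTSZ2 genes 1 of 11 was lower and the list did not pass (median -0.080, adjusted p = 0.0745). Abscisic acid genes did not pass, with none of 4 called in the list fixed in advance, over all genes or adjusted over the list alone (adjusted p = 0.733). In the added list of 15 (adjusted p = 0.962; median -0.045, mean 0.024) COR27 was higher by 0.82 (SE 0.14) and HIS1-3 (AT2G18050), a linker histone of drought response, by 0.57 (SE 0.13), while RD2 was lower by -0.61 (SE 0.11). The immunity and defence list did not pass (1 higher and 1 lower of 22, adjusted p = 0.272; median 0.20, mean -0.017). Phenylpropanoid genes (2 of 10 lower, adjusted p = 0.0939), tau-class glutathione transferases (1 of 4 lower, 0.14), SWEET transporters (1 of 5 lower, 0.142), autophagy (none of 10, 0.157), U-box ligases (1 of 8 higher, 0.297) and glucosinolate metabolism (1 of 9 lower, 0.438; median 0.00037, mean -0.27) did not pass. Calmodulin-like genes (none of 5, adjusted p = 0.477), cell wall expansion (none of 12, 0.517), CYP71B cytochromes (1 of 10 higher, 0.535), the tricarboxylic acid cycle and citrate list (none of 18, 0.702) and ubiquitin proteases and conjugases (2 of 22 higher, 0.736) did not pass. Carboxypeptidase-like genes (none of 13, adjusted p = 0.923, with a median of 0.0017 while the test pointed downward) and exocyst and SNARE genes (none of 14, 0.962) did not pass either.

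After Bgh 679 probe sets differed between genotypes (4.98% of those tested), 286 higher and 393 lower in ataf1-1, and 114 by at least 2-fold. Median centring gave 246 higher and 551 lower, and the replicate number as a block 469 higher and 549 lower (1018 in all). The un-inoculated and inoculated differences had 3 calls in common, 1 of them in the same direction. The count was 1134 without inoculated ataf1-1 replicate 1, an array that stood apart from its group, and 215 without inoculated ataf1-1 replicate 2. It was 343, 358 and 380 without inoculated wild-type replicates 1, 2 and 3, and 263 in a fit of these 2 groups alone. Of 33 genes named and called here, 13 passed without each array in turn, among them AT1G73600, JAL23, SBPASE, CYP71B24 and AT1G12010. The other 20 lost their call without at least 1 array, which for all but SNZ and HIS1-3 included inoculated ataf1-1 replicate 2. These leave-out fits did not use the replicate number as a block. Inoculated arrays with the same number deviated together, however, with residuals correlated at 0.446 for replicate 1, 0.132 for replicate 2 and 0.258 for replicate 3. With the block on all arrays no called gene named here lost its call.

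**Figure D3:**
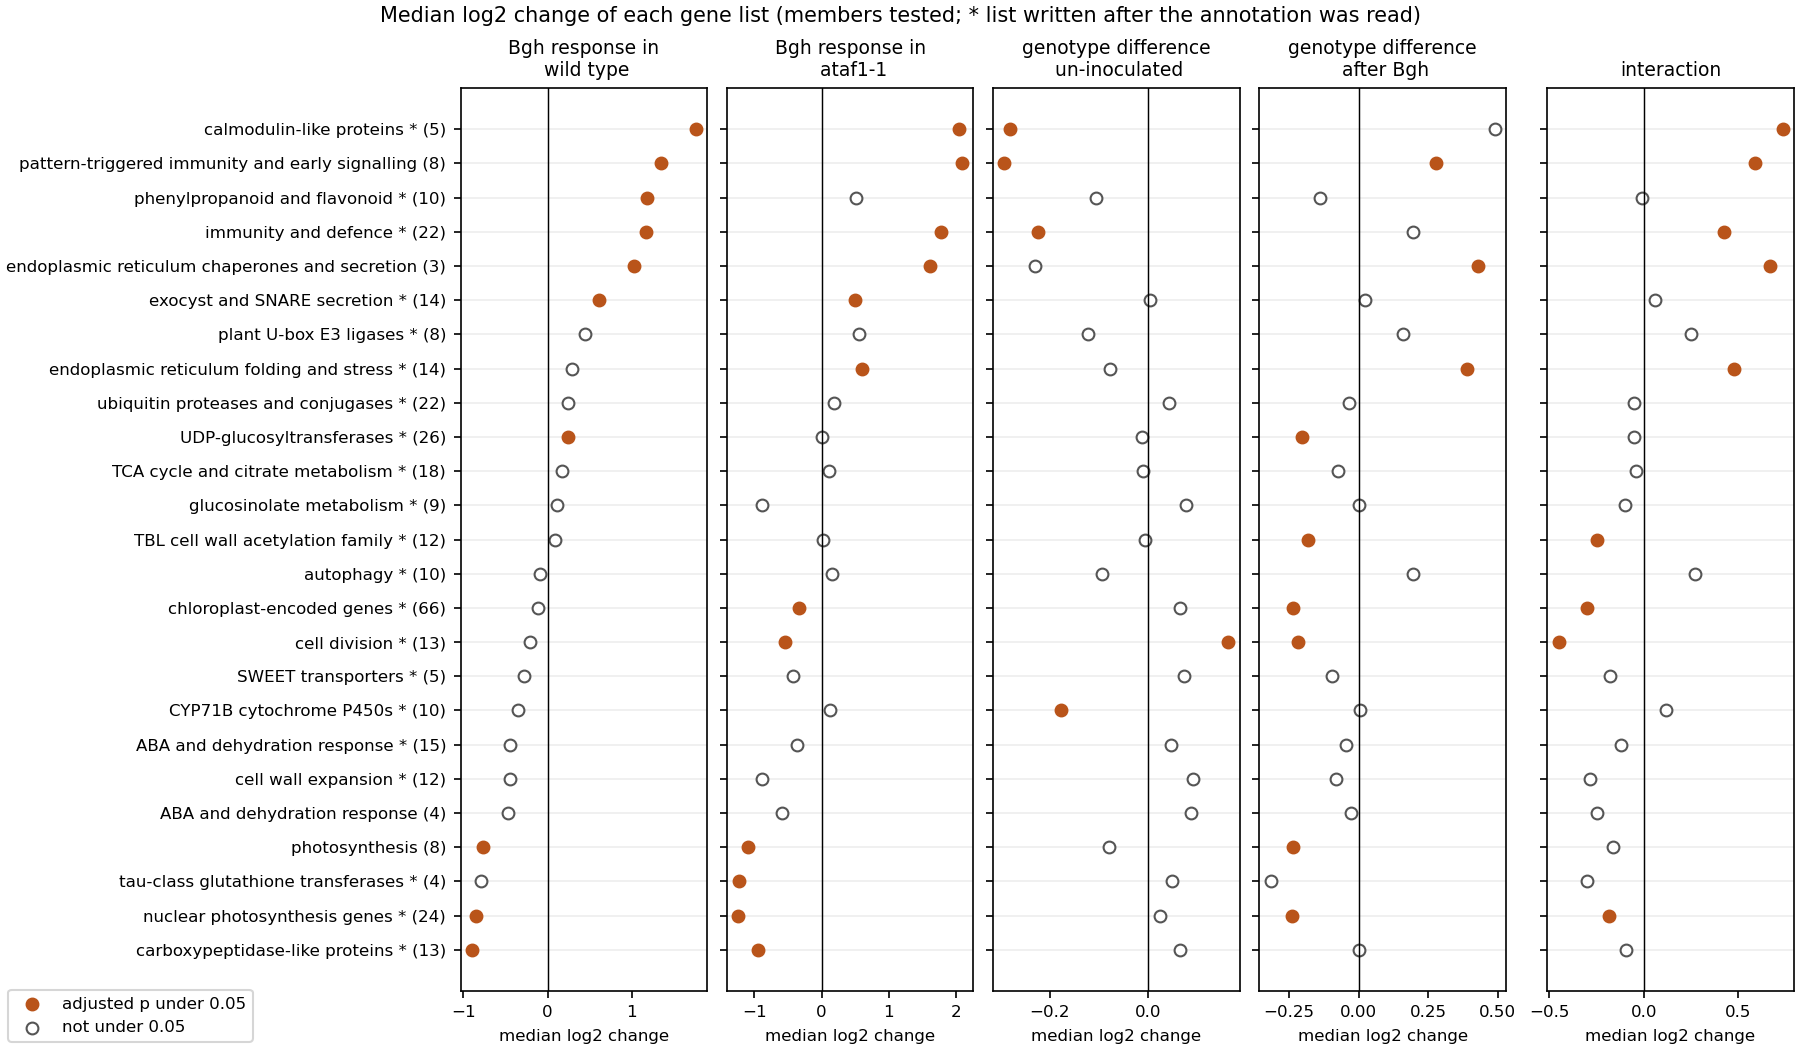
Median log2 change of each tested gene list in the 5 contrasts, with filled points for lists that passed at the preset correlation. Chloroplast-encoded genes lay at -0.24 and endoplasmic reticulum folding genes at 0.39 in ataf1-1 against wild type after Bgh.

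The interaction tests directly whether the response to Bgh differed between genotypes, and positive values mark a larger rise, or a smaller fall, in ataf1-1. In the immunity and defence list 19 of 22 genes had positive values, and 53 of 66 chloroplast-encoded genes had negative ones, though neither list passed with an estimated correlation (adjusted p = 0.204 and 0.333). SAL2 had 3.38 (SE 0.64, adjusted p = 0.0187), with a signal of 432.2 ± 189 and 226.8 ± 39.4 in wild type before and after Bgh and 208.3 ± 165 and 943.2 ± 63.8 in ataf1-1 (SD, n = 3). AT3G18250 had 2.34 (SE 0.35, adjusted p = 0.00926), AT2G42360 3.19 (SE 0.76), AT1G58420 2.66 (SE 0.60), AT5G55450, of the lipid transfer protein family, 2.36 (SE 0.48), and AT5G44820 2.35 (SE 0.44). CYP71B24 had 2.07 (SE 0.30, adjusted p = 0.00789), since it fell in wild type from 399.7 ± 62 to 115.4 ± 34.4 and stood at 291.1 ± 65.7 and 340.5 ± 35.9 in ataf1-1. CYP71B23 had 1.67 (SE 0.38). AT1G73600 had -1.33 (SE 0.17, adjusted p = 0.00437), and Cpn60beta2 (AT3G13470), a chaperonin of the chloroplast, -1.27 (SE 0.17, adjusted p = 0.00568), with mean signals of 1254 and 1652 in wild type and 1484 and 817.3 in ataf1-1 before and after Bgh. AT4G17470 had -1.60 (SE 0.29), GSTU20 -1.19 (SE 0.21), AT2G43550 -1.19 (SE 0.23) and BCAT4 -0.97 (SE 0.17), the last from 2163 ± 216 to 1666 ± 132 in wild type and from 3155 ± 201 to 1246 ± 190 in ataf1-1.

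Of 22 immunity and defence genes 1 passed in the interaction, SAG101 at 1.35 (SE 0.31), and the list passed (median 0.43, adjusted p = 0.00248; adjusted p = 0.204 with an estimated correlation). None of the 8 genes of pattern-triggered immunity passed over all genes and 4 did adjusted over the list alone (median 0.59, adjusted p = 0.00232; adjusted p = 0.264 with an estimated correlation). Nearest were WRKY53 (AT4G23810), a factor of immunity and senescence, at 1.3 (SE 0.33, adjusted p = 0.054), and CML37 at 2.17 (SE 0.58, adjusted p = 0.062). Of 5 calmodulin-like genes none passed and the list did (median 0.73, adjusted p = 0.0369; adjusted p = 0.228 with an estimated correlation). The 3 tested genes of the endoplasmic reticulum chaperone and secretion list passed adjusted over the list alone and none over all genes (median 0.67, adjusted p = 0.0116, or 0.264 with an estimated correlation). CRT1b stood at 0.67 (SE 0.20, adjusted p = 0.0881). In the wider folding list none of 14 passed alone (median 0.48, adjusted p = 0.000878; adjusted p = 0.249 with an estimated correlation).

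Of 66 chloroplast-encoded genes 1 passed in the interaction, rps15 at -1.25 (SE 0.24), with 493.6 ± 49.7 and 649.9 ± 90.9 in wild type and 713.7 ± 134 and 395.4 ± 80.9 in ataf1-1. The list passed (median -0.30, adjusted p = 7.66e-06; adjusted p = 0.333 with an estimated correlation), while the mean actin ratio moved from 2.35 to 2.3 in wild type and from 2.47 to 2.14 in ataf1-1, and that of GAPDH from 0.797 to 0.919 and from 0.783 to 0.981. Of 23 nuclear photosynthesis genes (without GAPC2) 2 passed (median -0.18, adjusted p = 0.00179; adjusted p = 0.326 with an estimated correlation), SBPASE at -0.62 (SE 0.12) and NTRC at -0.72 (SE 0.17). The photosynthesis list fixed in advance did not pass, with 1 of 8 called, 2 adjusted over the list alone (adjusted p = 0.0939). Of 13 cell division genes 1 passed, HTB4 at -0.69 (SE 0.12), which rose in wild type from 2085 ± 107 to 2769 ± 159 and fell in ataf1-1 from 2438 ± 121 to 2012 ± 76.5 (list median -0.45, adjusted p = 0.00201; adjusted p = 0.264 with an estimated correlation). Without the FTSZ2 genes the median was -0.21 (adjusted p = 0.0144; adjusted p = 0.275 with an estimated correlation). In the TBL family 1 of 12 passed, TBL37 at -0.64 (SE 0.15; median -0.25, adjusted p = 0.0405; adjusted p = 0.228 with an estimated correlation). COR27 had 0.88 (SE 0.20), RD2 -0.65 (SE 0.16) and ACLA-3 (AT1G09430), of ATP citrate lyase, 0.54 (SE 0.13). PDF1.2 did not pass (-1.22, SE 0.86, adjusted p = 0.487). None of the 4 genes of the fixed abscisic acid list passed, over all genes or adjusted over the list alone (adjusted p = 0.47). Autophagy (none of 10, adjusted p = 0.0592), tau-class glutathione transferases (1 of 4, 0.0803), CYP71B cytochromes (2 of 10, 0.0939), UDP-glucosyltransferases (none of 26, 0.157), SWEET transporters (none of 5, 0.157) and glucosinolate metabolism (1 of 9, 0.194) did not pass. Phenylpropanoid genes (none of 10, adjusted p = 0.32), U-box ligases (none of 8, 0.389), cell wall expansion (none of 12, 0.47) and carboxypeptidase-like genes (none of 13, 0.573) did not pass. Ubiquitin proteases and conjugases (none of 22, adjusted p = 0.844), the added abscisic acid list (2 of 15, 0.866, with a median of -0.12 and a mean of 0.088), the tricarboxylic acid cycle and citrate list (1 of 18, 0.886) and exocyst and SNARE genes (none of 14, 0.976, with a median of 0.062 and a mean of -0.0051) had the highest adjusted p. The list test asks for 1 direction, and the 2 genes called in the added abscisic acid list, COR27 and RD2, went opposite ways.

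In the interaction 316 probe sets passed (2.32%), 182 positive and 134 negative, and 160 by at least 2-fold (122 positive and 38 negative). The balance was 180 to 178 after median centring, 280 to 292 with array weights and 454 to 478 without inoculated ataf1-1 replicate 1. Without un-inoculated ataf1-1 replicate 2 it was 237 to 112, so the balance moved both ways. Of the positive ones 115 rose and 40 fell with Bgh on average, and of the negative ones 27 rose and 87 fell. The count was 932 without inoculated ataf1-1 replicate 1 and 79 without inoculated ataf1-1 replicate 2. It was 93, 123 and 149 without un-inoculated wild-type replicates 1, 2 and 3, 112 and 200 without inoculated wild-type replicates 1 and 3, 162 and 136 without un-inoculated ataf1-1 replicates 1 and 3, and 210 without inoculated ataf1-1 replicate 3. Of 23 genes named and called here, AT3G18250, AT4G17470, AT1G73600, Cpn60beta2, GSTU20, BCAT4, HTB4 and CYP71B24 passed without each array. The other 15 lost their call without at least 1 array, inoculated ataf1-1 replicate 2 for all of them, with adjusted p up to 0.108.

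**Figure D4:**
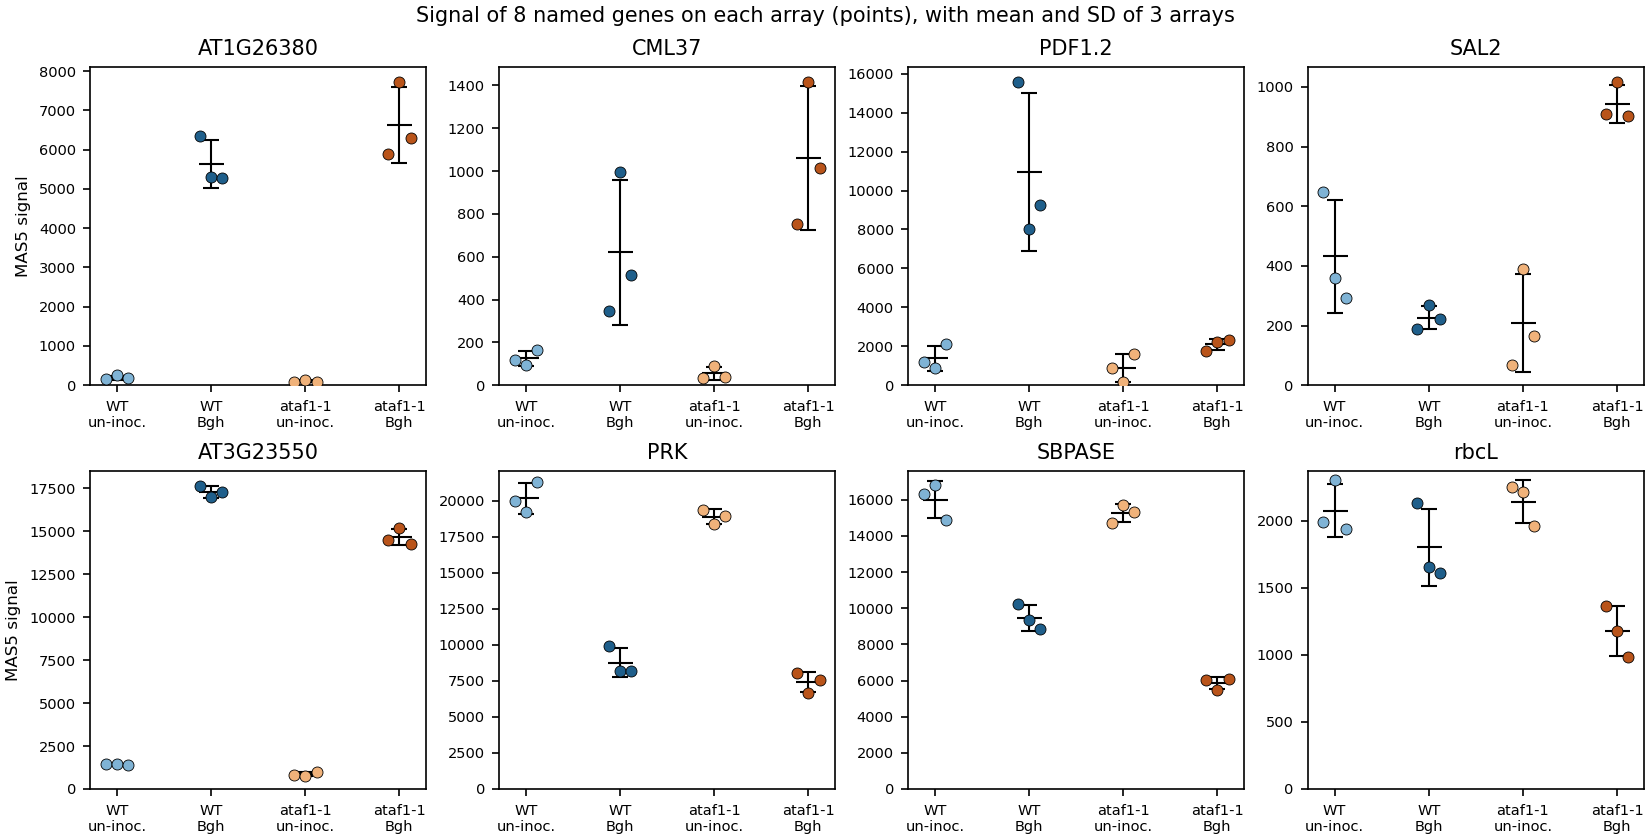
Signal per array in the 4 groups for genes named in the comparisons, with 1 point per array and the group mean. SAL2 had a mean of 943.2 in inoculated ataf1-1 and 226.8 in inoculated wild type.

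Averaged over both genotypes 9668 probe sets (70.8%) differed between inoculated and un-inoculated rosettes, 3879 higher and 5789 lower after Bgh, and 3167 by at least 2-fold. Averaged over both states 127 probe sets differed between genotypes (0.931%), 34 higher and 93 lower in ataf1-1, and 12 by at least 2-fold. The clearest average genotype effect, chosen after its value was seen, was of a probe set for which no gene name was used. It was higher in ataf1-1 by 2.32 (SE 0.075, adjusted p = 3.93e-10), at 3899 ± 208 against 770.2 ± 28.7 before and 3775 ± 410 against 766 ± 76.4 after Bgh (SD, n = 3). The largest average fall of a probe set lower in both states, also without a gene name, was -1.97 (adjusted p = 0.0133). AT1G73600 and AT1G62660 had average differences of -0.63 (SE 0.082, adjusted p = 0.00748) and -0.64 (SE 0.088, adjusted p = 0.00968). The count of 127 was 74, 29 and 69 without un-inoculated wild-type replicates 1, 2 and 3, and 72 and 78 without inoculated wild-type replicates 2 and 3. It was 65 without un-inoculated ataf1-1 replicate 1 and 60 without inoculated ataf1-1 replicate 2. It was 63 with no intensity trend and 84 with no filter.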

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

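No test in this part was chosen after its result was seen except those of 2 lists without some members, while the gene lists other than those fixed in advance were written after the gene names were read. Every result here is given because the response to Bgh differed between the genotypes by the test of the interaction, log2 change in ataf1-1 minus that in wild type. In all 316 probe sets passed. In splits of the genotype labels within treatment the highest other count was 90 and 1 of 100 splits, the real one, gave as many. This makes chance unlikely for the count and does not exclude it. The splits were a sample of those possible, and the count fell to 79 without inoculated ataf1-1 replicate 2.

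The largest positive values of named genes were those of SAL2, AT2G42360, AT1G58420, AT5G55450, AT5G44820 and AT3G18250, at 3.378, 3.191, 2.661, 2.362, 2.351 and 2.342, and the EDS1 partner SAG101 had 1.353. CYP71B24 and CYP71B23, of a cytochrome family, had 2.065 and 1.667, COR27 0.8763 and ACLA-3 0.5431. AT4G17470, AT1G73600, AT2G43550 and the glutathione transferase gene GSTU20 had -1.598, -1.328, -1.188 and -1.192. For genes of the chloroplast the values were -1.274 for Cpn60beta2, -1.249 for rps15, -0.6209 for SBPASE and -0.7227 for NTRC. BCAT4 had -0.9739, the histone gene HTB4 -0.6855, RD2 -0.6546 and TBL37 -0.6367. Of these 23 genes 8 passed without each array in turn, and 15 lost their call without inoculated ataf1-1 replicate 2 or further arrays, with adjusted p up to 0.108.

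Lists that differed had median interactions of 0.59 for pattern-triggered immunity, 0.425 for immunity and defence, 0.734 for calmodulin-like proteins, 0.667 for endoplasmic reticulum chaperones and 0.475 for endoplasmic reticulum folding (0.439 without ATCRT1). The medians were -0.297 for chloroplast-encoded genes, -0.181 for nuclear photosynthesis genes, -0.45 for the cell division list (-0.207 without its 2 genes of chloroplast division) and -0.248 for the TBL family. None of these lists passed with an estimated correlation, where adjusted p was 0.204 or higher for all 9 of them.

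The first pattern weighed was a larger response to Bgh in ataf1-1, seen as a slope of 0.164 of the interaction on the average Bgh effect over all tested probe sets. A single array as the whole cause was argued against, since the slope stayed at 0.122 or more without each array, and so were unequal signal distributions, since it was 0.16 after quantile normalization. The un-inoculated genotype difference had a slope of -0.126 and made up 77% of the pattern (51% to 103% without 1 array), which is consistent with un-inoculated wild-type rosettes already being partly induced, by genotype or by growing conditions, which were not told apart. The highest slope of other splits was 0.217, above the real 0.164, and 11 of 100 splits gave one as large, so chance could not be excluded. After Bgh the genotype difference had a slope of 0.0377 (-0.0035 to 0.118 without 1 array), so these values do not show a higher induced level in ataf1-1, and a biological difference in the response was not tested.

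The second pattern was a median interaction of -0.297 for 66 chloroplast-encoded transcripts, lower in ataf1-1. The generally larger response as its whole cause was argued against by the median of -0.239 left after taking that slope off (-0.314 to -0.147 without 1 array), and a single array by -0.183 as the median nearest 0 without 1 array. Labelling of organelle RNA in general was argued against for the interaction by 0.0228 for 9 mitochondrion-encoded transcripts (-0.0605 to 0.102), but stays open for the genotype difference after Bgh alone, where they had a median of -0.127 against -0.236 for the chloroplast. RNA degradation cannot be told apart, since with the actin 3′ to 5′ ratio as a covariate the median was -0.266 with all arrays and -0.0474 without inoculated ataf1-1 replicate 2, while the GAPDH ratio was higher, not lower, in ataf1-1 after Bgh (0.981 against 0.919 in wild type). The largest median of other splits was 0.359 in size, above the real 0.297, and 9 of 100 splits were as large, so chance could not be excluded, and a biological difference between the genotypes was not tested.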

How the results depend on the processing

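Of the alternatives in this part only the lists without some members were chosen after results were seen, while 21 of the 25 gene lists tested were written after gene names were read. No called gene named in the text changed direction under the alternatives run for genes, all but the fit of only 2 groups and the 2-fold threshold, and no called list with an estimated correlation, fry, quantile normalization or the block. Medians near 0 of lists that did not pass changed sign after quantile normalization or median centring, for photosynthesis, the TBL family and exocyst and SNARE genes before Bgh, and for exocyst and SNARE, glucosinolate, CYP71B and carboxypeptidase-like genes after it. More interactions were positive than negative (182 and 134), and also with the replicate number as a block (467 and 294). This was not so with array weights (280 and 292) or without inoculated ataf1-1 replicate 1 (454 and 478). The counts of both Bgh responses and of the average Bgh effect stayed within 1.5 times their size in every alternative except the 2-fold threshold, and median centring, quantile normalization, a pseudocount and the upper 40% left all 7 counts within that range.

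A threshold of 2-fold lowered the counts, by its construction, to 2966 and 3613 for the response in wild type and ataf1-1, 6 and 114 for the genotype difference before and after Bgh, 160 for the interaction, and 3167 and 12 for the average effects of Bgh and genotype. For the un-inoculated genotype difference the count of 18 became 7 with no filter, 1 with no intensity trend, 69 with array weights and 1 with only the 2 groups compared, a fit with fewer arrays. For the difference after Bgh the count of 679 became 431 with no trend and 263 with only the 2 groups compared. The interaction count of 316 became 157 with no trend and 572 with array weights, and the average genotype count of 127 became 63 with no trend and 84 with no filter. The cause was not tested except where named. The replicate number as a block gave 86 for the un-inoculated difference, 1018 (against 679) for the difference after Bgh, 761 for the interaction and 220 for the average genotype effect, and 8171, 8491 and 9770 for the Bgh responses and their average. Of 18 pairs of arrays with the same number 12 had residuals correlated at over 0.1 (-0.0593 to 0.446, mean 0.123, against a mean of -0.0602 for other pairs), and 7 of 12 arrays correlated best with their own number, not all. All 6 pairs of number 1 lay between 0.114 and 0.446, a hint from the data of something these arrays shared. With the block 5 named values gained a call, SBT3.3 before Bgh, BZIP60 after it and WRKY53, CML37 and CRT1b in the interaction, and no called gene or list lost one.

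Leaving out 1 array gave 7180 to 8205 in wild type, 7567 to 8434 in ataf1-1 and 9314 to 9683 for the average Bgh effect. It gave 1 (without wild-type un-inoculated replicate 1) to 59 (without ataf1-1 un-inoculated replicate 2) for the un-inoculated difference, and for the difference after Bgh 215 (without inoculated ataf1-1 replicate 2) to 1134 (without replicate 1 of that group). For the interaction it gave 79 to 932, without the same 2 arrays. The average genotype effect ranged from 29 (without wild-type un-inoculated replicate 2) to 151 (without inoculated ataf1-1 replicate 1). The correlation of the responses, 0.907, was 0.61 with no filter, when probe sets of low signal entered, 0.922 in the upper 40% and 0.893 to 0.915 without 1 array.

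Of 45 list calls 0 passed with limma's camera at an estimated correlation, against 45 at the preset one and 61 tests with fry, which shared 37 of the 45. Quantile normalization kept 43. Without FTSZ2-1 and FTSZ2-2 the cell division list no longer passed in ataf1-1 (adjusted p 0.0776) and after Bgh (0.0745) and passed before Bgh (0.0306) and in the interaction (0.0144, with a median of -0.21 against -0.45), and without ATCRT1 the endoplasmic reticulum folding list passed where it had (0.00113 to 0.00339). So did nuclear photosynthesis without GAPC2 (8.24e-07 to 0.00179), and the tricarboxylic acid cycle and citrate list without 10 genes passed in both Bgh responses, which the full list did not. Of 3115 comparisons of 158 values for named genes with an alternative, 2803 stayed on the same side of the threshold, 295 lost the call and 17 gained one, and 51 of the 158 changed in at least 1. Without the trend 23 calls were lost, with no filter 17, with quantile normalization 6 and with array weights 3. The alternatives for ATAF1 were not run. Signal over background limits what can be seen, since probe sets with a mean signal under 79.4 were not tested, and the call rate of the arrays was not analysed here.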

Other observations

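No test in this part was chosen after its result was seen except the shorter list of tricarboxylic acid cycle and citrate genes, and the genes of the first 2 paragraphs are members of tested lists picked after their values were seen. The receptor of bacterial elongation factor Tu, EFR, rose with Bgh by 1.49 in wild type and 2.63 in ataf1-1 (adjusted p = 0.00418 and 3.87e-05), although the inoculum was a fungus. ChiC, a chitinase, rose by 1.97 and 2.29, and SBT3.3 by 3.04 and 5.12. THE1, a receptor kinase that senses the state of the cell wall, fell by 1.09 on the log2 scale in wild type and changed by -0.65 in ataf1-1. None of these 4 passed in the interaction (adjusted p 0.215 to 0.634).

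The list of tricarboxylic acid cycle and citrate genes did not pass in either genotype (adjusted p = 0.155 and 0.195), and passed in both (0.00403 and 0.0144) without genes of ATP citrate lyase, leucine breakdown and electron transfer. Most members that fell in wild type were among those left out (5 of 18 fell in the full list, 1 of 8 in the shorter). The passes of the shorter list are thus not independent of that choice. With an estimated correlation the shorter list had an adjusted p of 0.227 and 0.253. The succinate dehydrogenase subunits SDH1-1, SDH2-1 and SDH2-2 rose by 1.13, 0.85 and 0.81 in wild type and by 0.86, 0.70 and 0.69 in ataf1-1, and the isocitrate dehydrogenase subunits IDH-V and IDH-VI by 0.70 and 0.84 in wild type. The ATP citrate lyase genes ACLB-1 and ACLA-2 fell in wild type, with -0.75 and -0.51, while ACLA-3 rose by 0.25 (adjusted p = 0.0287). Autophagy genes split too, with ATG8F and ATG8C at -0.80 and -0.70 and ATG8H at 0.49 in wild type. SWEET17, a fructose transporter of the vacuole, rose by 0.93 and SWEET2, a glucose transporter of the vacuole, changed by -0.88.

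For other counts the labels were split anew. The average effect of Bgh called 9668 probe sets and the highest other of 100 splits 5092, and the average effect of genotype 127 and the highest other 100. In each case 1 of 100 splits, the real one, gave as many. The splits were a sample of those possible, so chance is unlikely but not excluded. For genotype the margin was narrow, and without wild-type un-inoculated replicate 2 the count of 127 fell to 29. Pairwise comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. In these, 1 of 10 gave as many as the real one, which called 8032 in wild type and 8352 in ataf1-1 (highest other 0 in both, by limma in the fit described), 18 before Bgh (highest other 1) and 679 after it (highest other 46).

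The 25S rRNA probe set read 416 ± 146 and 274 ± 102 in wild type before and after Bgh and 602 ± 223 and 248 ± 57.3 in ataf1-1 (SD, n = 3). The ranges overlapped in wild type (267.6 to 558.5 and 206.6 to 390.7), and the mean of 602 rests in part on 1 array at 859.2.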
